A study of Homo sapiens with 12 samples.

How the data were processed

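Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on 2 human colorectal adenocarcinoma cell lines, SW480 and SW620, grown untreated in DMEM, per the labels. The antibodies recognised the histone modifications H3K4me2, H3K4me3, H3K27ac and H3K36me3 and the transcription factor FOXA2. An input library of each line was also labelled, so that 12 samples formed 12 groups with 1 library each. The 10 antibody libraries each had a list of enriched regions. Groups were taken from the sample titles.

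The authors called regions separately in each library with HOMER findPeaks against the input of the same line, per the file headers. Histone marks were called in the histone style with a region size of 1000 bp, a minimum of 4-fold over input (option F), a minimum of 4-fold over the local background (option L) and a false discovery rate of 0.001. FOXA2 peaks were called in the factor style with both minimum enrichments at 2 and the same false discovery rate, and were centred, per the file headers. The genome build was hg19 per the submitters' processing notes. The aligner and the version of HOMER are not given in the sources used here.

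Each deposited list has 6 columns. The deposited score column held 1 in every row of the 10 lists, so no signal per region was analysed here. The other deposited values used were the start and end positions of each region in bp, as the authors' caller gave them. Total tags, tags in regions, fragment length and the share of tags in regions were read from the file headers. The number of rows equalled the total given in the header of each of the 10 lists. Total tags per library lay between 12791745 and 47867295.

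Regions were compared by position. A region counted as shared when it overlapped a region of the other line by at least 1 bp, and as line-only otherwise. Overlaps between lines were computed with numpy 2.4.6 and pandas 2.3.3 in Python 3.11.15 and checked against bedtools 2.31.1, which also gave the overlaps by fraction. Shares carry 95% Wilson intervals from scipy 1.17.1. These intervals cover counting error only, and neighbouring regions are not independent. As a background, the regions of each list were placed at random on their own chromosome 100 times, over the stretch that the 10 lists span, with a fixed seed. The functions were tested on simulated regions with known answers, using 2000 regions per antibody. They assigned 100% of these regions correctly for each of the 5 antibodies.

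With 1 library per group no test between the lines was possible and no p-value is given. A region called in one list alone can fall just below the threshold in the other, so line-only describes the lists. Because no score was usable, histone regions were ranked by width, as fixed before the data were examined. FOXA2 peaks have one width per list, 127 bp in SW480 and 319 bp in SW620, and were ranked by their order in the list. That choice was made after the files were seen, and whether list order follows peak strength is not given in the sources used here. H3K27ac regions overlapping H3K4me3 of the same line were called promoter-like and the rest enhancer-like.

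The comparisons, the overlap rule, the alternatives and the rule for named regions were otherwise chosen before the data were examined. The rule took, per direction, the 10 widest H3K27ac regions with no H3K27ac region of the other line within 5 kb. It also took the first 10 line-only FOXA2 peaks that overlap H3K27ac in their own line alone, and the 5 widest H3K4me3 regions of each line. The share of marked regions holding a FOXA2 peak, the division of the FOXA2 lists into 10 equal parts by order and the windows of 5 Mb were chosen after the data were seen. A window was used where each of H3K4me2, H3K27ac and H3K36me3 had at least 10 line-only regions. Its excess was the log2 ratio of SW620-only to SW480-only regions, each plus 1, minus the log2 ratio over all windows. The 5 windows per direction in which the least extreme of the 3 marks had the largest excess were named.

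The gene table at hand is on GRCh38. Its gene ends were set against the H3K4me3 regions once, to check the build, and its coordinates were used for no result. Only 8.10% of SW480 and 8.50% of SW620 H3K4me3 regions covered a gene end of that table. After a move of 500 kb the shares were 5.04% and 5.05%. Regions are therefore named by hg19 coordinates, counted from 1. Promoter states of genes, H3K36me3 over gene bodies, the gene lists fixed beforehand, FOXA2 peaks near genes and the forkhead motif were not analysed here. The input libraries were not used here beyond the authors' peak calling. Alternatives covered the overlap rule, the ranking, list length, the chromosomes used and the peak width. Figures were drawn with matplotlib 3.10.9.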

Results

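The series profiled active chromatin and FOXA2 binding in SW480 and SW620, colorectal adenocarcinoma cell lines that the labels describe as Dukes' type B and Dukes' type C. By general knowledge of these lines, and not by the labels, SW480 came from a primary colon tumour and SW620 from a metastasis of the same patient. The series title places the comparison in the setting of liver metastasis and tissue-specific transcription. That setting is not a statement of the site from which SW620 was taken. H3K4me3 marks promoters, H3K4me2 marks promoters and enhancers, H3K27ac marks active promoters and enhancers, and H3K36me3 covers transcribed gene bodies. FOXA2 is a forkhead factor of foregut endoderm and liver. Each line contributed 1 library per antibody, so differences between lines have no replicate check. Intervals are 95% Wilson intervals that cover counting error only. Coordinates are hg19.

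The first comparison asked how much chromatin each line marked. H3K4me2 covered 78.8 Mb in 31768 regions in SW480 and 84.8 Mb in 35114 regions in SW620. H3K4me3 covered 41.2 Mb in 18296 SW480 regions and 36.9 Mb in 16315 SW620 regions. H3K27ac covered 64.5 Mb in 23493 SW480 regions and 56.1 Mb in 22236 SW620 regions. H3K36me3 covered 145 Mb in 52664 SW480 regions and 135 Mb in 45466 SW620 regions. The number of regions in SW620 relative to SW480 thus lay between 0.863 for H3K36me3 and 1.11 for H3K4me2. Mean widths were 2484 and 2420 bp for H3K4me2, 2252 and 2261 bp for H3K4me3, 2748 and 2529 bp for H3K27ac, and 2784 and 3011 bp for H3K36me3, with SW480 first.

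FOXA2 stood apart from the histone marks. SW620 had 12372 FOXA2 peaks and SW480 had 5207, a ratio of 2.38. The covered length was 3.95 Mb in SW620 and 0.661 Mb in SW480, with mean peak widths of 319 and 127 bp. These widths follow the caller's peak size for each library, 318 bp in SW620 and 126 bp in SW480, and so does the covered length. When the count was limited to peaks on H3K4me2 of their own line, 6392 in SW620 and 292 in SW480, the ratio was 21.9. The FOXA2 libraries had similar depth, 19473583 tags in SW480 and 18036456 in SW620, but 0.590% of the SW480 tags and 2.25% of the SW620 tags lay in peaks. The H3K27ac libraries also differed in this share, with 58.5% of 34224728 tags in SW480 and 27.5% of 47867295 tags in SW620. For H3K4me3 it was 73.0% of 16400013 tags in SW480 and 52.0% of 12791745 in SW620. For H3K4me2 it was 45.8% of 20958795 and 50.7% of 23671100, and for H3K36me3 32.8% of 37446361 and 35.2% of 46006580.

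The lines were then compared region by region. H3K4me3 was the mark most often found in both lines: 82.9% of SW480 regions (82.4 to 83.5) overlapped an SW620 region, and 93.1% of SW620 regions (92.7 to 93.5) overlapped an SW480 region. For H3K4me2 the shares were 76.8% (76.4 to 77.3) of the SW480 list and 69.8% (69.3 to 70.3) of the SW620 list. For H3K27ac they were 68.0% (67.4 to 68.6) and 73.2% (72.6 to 73.7), and for H3K36me3 65.7% (65.3 to 66.2) and 72.1% (71.6 to 72.5). Randomly placed histone regions reached a mean of between 2.93% and 8.71%. Measured by length, 67.3% of all H3K4me3-covered sequence was covered in both lines, against 52.7% for H3K4me2, 49.7% for H3K36me3 and 48.2% for H3K27ac. Line-only regions were the narrower ones. The median width of SW480-only H3K27ac regions was 1763 bp and that of shared ones 2651 bp, and in the SW620 list the medians were 1519 and 2378 bp. When an overlap of at least 50% of both regions was required, the H3K36me3 shares were 30.5% and 35.3%. With equal numbers of the widest regions from both lines, the order of the H3K36me3 shares turned, with 70.4% for SW480 and 68.3% for SW620.

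**Figure D1:**
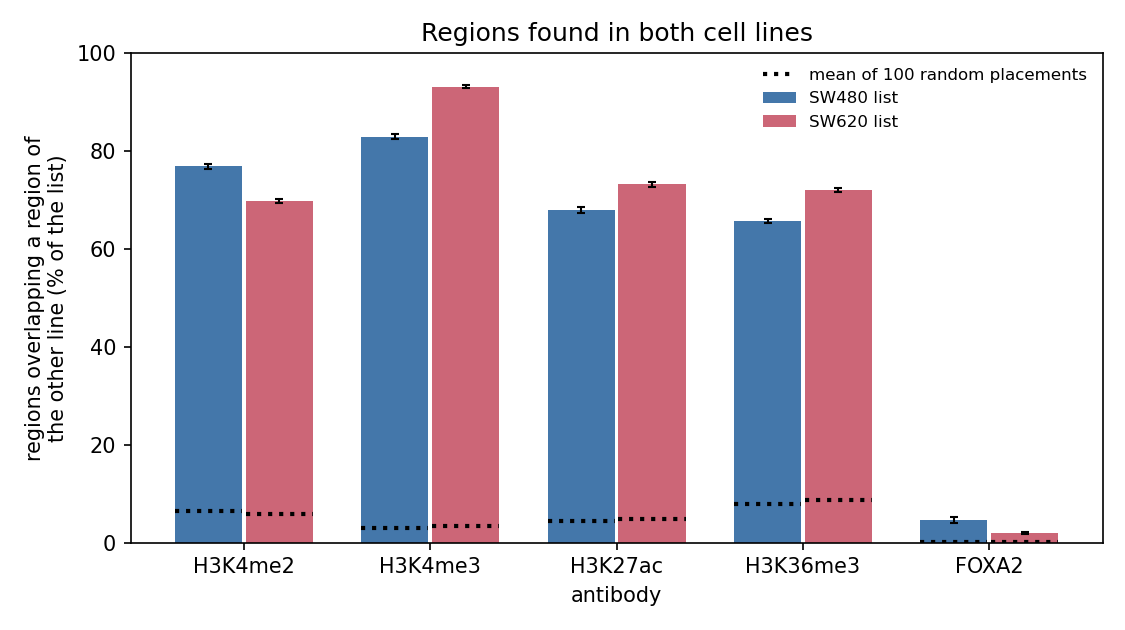
Share of the regions of each list (vertical axis, % of the list) that overlapped a region of the other cell line, by antibody (horizontal axis), with 95% Wilson intervals and 1 library per bar. Dotted lines give the mean of 100 random placements. H3K4me3 reached 82.9% and 93.1%, and FOXA2 4.53% and 1.91%.

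Promoter-like and enhancer-like H3K27ac regions were compared separately. Acetylated regions with H3K4me3 were mostly found in both lines: 81.2% (80.6 to 81.8) of 15747 SW480 regions and 95.2% (94.9 to 95.6) of 13317 SW620 regions. Acetylated regions without H3K4me3 were found in the other line in 41.1% (40.0 to 42.2) of 7746 SW480 cases and 40.2% (39.2 to 41.2) of 8919 SW620 cases. H3K4me2 had the same division. With H3K4me3, 95.7% of SW480 and 96.0% of SW620 H3K4me2 regions were found in the other line. Without it the shares were 52.6% (51.8 to 53.4) and 47.8% (47.1 to 48.5). These classes were not matched on width, and regions with H3K4me3 were the wider ones. For H3K27ac the median widths, SW480 first, were 2549 and 2375 bp with H3K4me3 and 2043 and 1777 bp without it. For H3K4me2 they were 2897 and 3049 bp with it and 1415 and 1511 bp without it. How much of the division follows from width was not tested. Enhancer-like regions made up 33.0% of the SW480 and 40.1% of the SW620 H3K27ac list. This class rests on a missing H3K4me3 call, and the SW620 H3K4me3 library had fewer tags and a lower share of tags in regions. With H3K4me3 of either line within 1 kb counted, 7341 of 23493 SW480 and 8204 of 22236 SW620 regions were without it.

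Marks within a line fell together in the pattern known for active chromatin. In SW480, 98.9% of H3K4me3 regions overlapped H3K4me2 and 87.1% overlapped H3K27ac. In SW620 the shares were 99.4% and 82.2%. H3K27ac regions overlapped H3K4me2 in 92.3% of cases in SW480 and 91.3% in SW620. H3K36me3 regions overlapped the other histone marks in under 10% of cases, though for H3K4me2 and H3K27ac more often than randomly placed ones. With SW480 first, 8.76% and 9.37% lay on H3K4me2 against random means of 6.11% and 6.66%, and 7.33% and 7.28% on H3K27ac against 4.81% and 4.38%. On H3K4me3 the shares were 3.71% and 3.60%, against means of 3.48% and 3.22% and highest values of 3.70% and 3.47%. Random placement was uniform over each chromosome, including stretches without any called region, which lowers these means. No excess on H3K4me3 is therefore read from so small a difference.

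The FOXA2 lists of the lines had few positions in common. Of the SW480 peaks, 236 overlapped an SW620 peak, which is 4.53% (4.00 to 5.13) of the SW480 list and 1.91% (1.68 to 2.16) of the SW620 list. Random placements gave a mean of 0.175% for the SW480 list, so shared positions were 25.8 times as frequent as that. This background was uniform over each chromosome, and what the shared positions have in common was not tested. Of the 236 shared SW480 peaks, 128 (54.2%) lay on H3K4me2 in neither line. With equal numbers of first-listed peaks, 3.28% of either list was shared.

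FOXA2 peaks of SW620 lay largely on marked chromatin and those of SW480 mostly did not. In SW620, 51.7% of peaks (50.8 to 52.5) overlapped H3K4me2 of the same line, 33.9% (33.0 to 34.7) H3K27ac and 13.1% (12.5 to 13.7) H3K4me3. Random placement gave means of 3.38%, 2.24% and 1.50%. In SW480 the shares were 5.61% (5.02 to 6.27) on H3K4me2, 4.47% (3.95 to 5.07) on H3K27ac and 2.19% (1.83 to 2.62) on H3K4me3, against random means of 2.85%, 2.31% and 1.50%. Both lists were below the random mean on H3K36me3, with 2.63% against 5.17% in SW480 and 3.31% against 5.27% in SW620. Peaks of SW620 also overlapped marked chromatin of SW480, with 30.2% on SW480 H3K4me2 and 24.3% on SW480 H3K27ac.

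**Figure D2:**
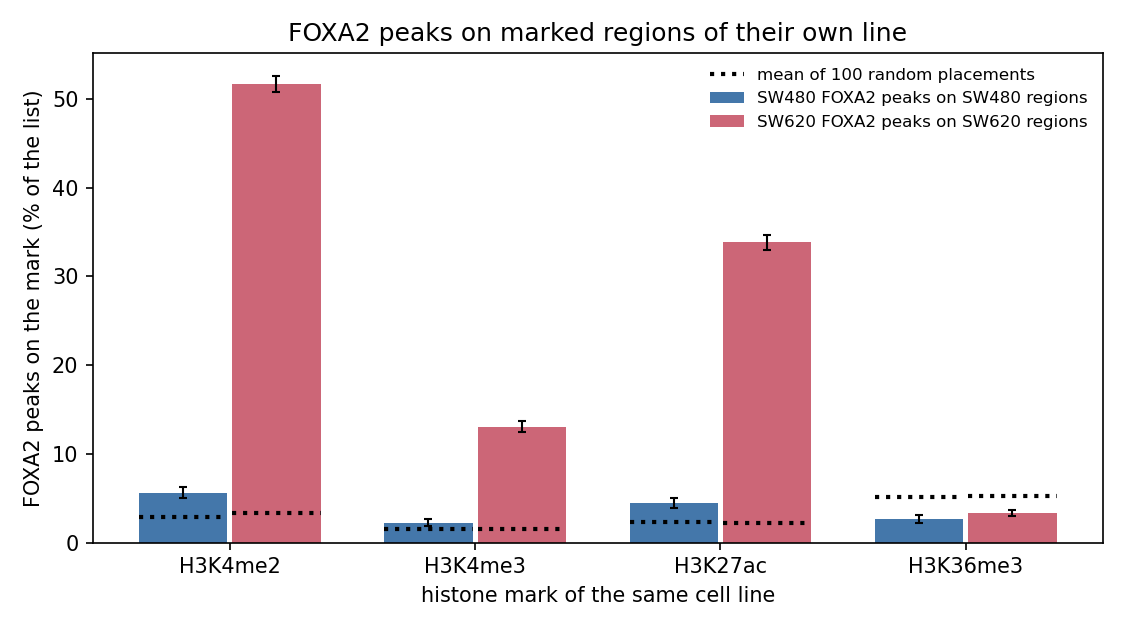
Share of FOXA2 peaks (vertical axis, % of the list) that overlapped a histone mark (horizontal axis) of the same cell line, with 95% Wilson intervals and 1 library per bar. Dotted lines give the mean of 100 random placements. SW620 peaks overlapped H3K4me2 in 51.7% of cases and SW480 peaks in 5.61%.

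At the 12136 FOXA2 peaks called in SW620 alone, active marks were more frequent in SW620 than in SW480. H3K27ac covered 34.1% (33.2 to 34.9) of them in SW620 and 24.2% (23.4 to 24.9) in SW480. Of these peaks, 2320 were acetylated in both lines, 1814 in SW620 alone and 614 in SW480 alone. For H3K4me2 the shares were 51.9% (51.0 to 52.8) in SW620 and 30.1% (29.3 to 30.9) in SW480, with 3024 peaks marked in SW620 alone and 374 in SW480 alone. H3K4me3 was as frequent in either line, with 13.2% (12.6 to 13.8) in SW620 and 13.1% (12.5 to 13.7) in SW480.

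The difference lay at sites without the promoter mark. In SW620, 23.7% of the SW620-only peaks had H3K27ac without H3K4me3 and 18.6% had H3K4me2 as their one active mark, while 44.5% had none of these 3 marks. At the same positions in SW480 the shares were 13.2%, 6.79% and 66.9%. Of the 4971 peaks called in SW480 alone, 94.9% had none of the 3 marks in SW480. H3K27ac covered 3.30% (2.84 to 3.83) of them in SW480 and 2.15% (1.78 to 2.59) in SW620. When H3K27ac within 1 kb was counted, these shares were 4.97% and 3.72%. The 236 peaks of the SW480 list that were shared overlapped H3K4me2 in 34.7% (29.0 to 41.0) of cases in SW480 and 37.7% (31.8 to 44.0) in SW620.

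Marked regions were also sorted by the line in which they were called, a division made after the data were seen. SW620 FOXA2 peaks lay in 26.7% (25.6 to 27.8) of the 5966 SW620-only H3K27ac regions, 14.3% (13.8 to 14.8) of the shared ones and 7.04% (6.48 to 7.64) of the 7519 SW480-only ones. For H3K4me2 the shares were 25.5% (24.7 to 26.3), 14.0% (13.6 to 14.5) and 4.09% (3.66 to 4.56). For H3K4me3 they were 24.2% (21.7 to 26.7), 8.56% (8.13 to 9.02) and 7.85% (6.95 to 8.84). For H3K36me3 they were 0.669% (0.541 to 0.826), 0.980% (0.879 to 1.09) and 0.904% (0.776 to 1.05).

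The acetylated regions were sorted further by H3K4me3. SW620-only regions held FOXA2 peaks no more often than shared ones among enhancer-like regions, and more often among promoter-like ones. These classes were not matched on width. Enhancer-like regions had a median width of 1515 bp when SW620-only and 2294 bp when shared. Without H3K4me3, 26.5% (25.3 to 27.7) of SW620-only and 29.9% (28.4 to 31.4) of shared regions held a peak, against 7.74% (7.00 to 8.55) of SW480-only regions. With H3K4me3 the shares were 28.3% (24.9 to 31.9), 9.89% (9.38 to 10.4) and 5.95% (5.15 to 6.86). With the first-listed 50% of the SW620 peaks alone, the enhancer-like shares were 16.8% in SW620-only, 18.5% in shared and 4.12% in SW480-only regions. SW480 FOXA2 peaks lay in 0.469% (0.325 to 0.677) of SW620-only and 1.20% (0.975 to 1.47) of SW480-only H3K27ac regions.

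**Figure D3:**
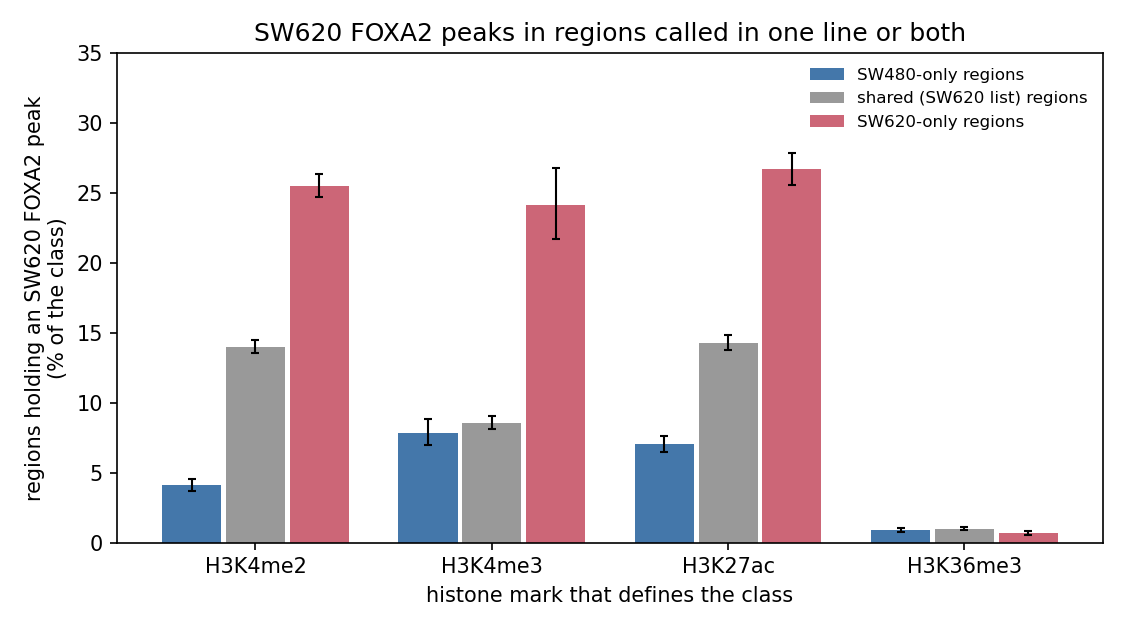
Share of marked regions (vertical axis, % of the class) that held an SW620 FOXA2 peak, for regions called in SW480 only, in both lines (SW620 list) and in SW620 only, by histone mark (horizontal axis), with 95% Wilson intervals. For H3K27ac the shares were 7.04%, 14.3% and 26.7%.

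Wide H3K27ac regions called in one line alone were described individually. The 10 widest SW620-only regions were 10.3 to 22.6 kb wide, and all 10 overlapped H3K4me2 in SW620, while 2 did in SW480. SW620 FOXA2 peaks lay in 9 of the 10. The widest, on chromosome 4 from 74461127 to 74483757, spanned 22.6 kb with 5 H3K4me2 regions, 1 H3K4me3 region, 4 H3K36me3 regions and 3 FOXA2 peaks in SW620, and no region of any of these in SW480. On chromosome 12, the region from 92244063 to 92263493 held 7 H3K4me2 and 3 H3K4me3 regions in SW620 and none in SW480, with 1 FOXA2 peak in each line. A cluster of 3 of the 10, of which 2 overlap each other by position, lay on chromosome 12 between 76048562 and 76121948. Each held 1 SW620 FOXA2 peak, which may be the same peak in the 2 that overlap. On chromosome 10, the region from 129676680 to 129692444 held 2 SW620 FOXA2 peaks, as did the one on chromosome 14 from 54633933 to 54647101.

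The 10 widest SW480-only H3K27ac regions were 12.3 to 26.8 kb wide. Of these, 8 overlapped H3K4me2 and 7 overlapped H3K4me3 in SW480, while 2 overlapped H3K4me2 and none H3K4me3 in SW620. SW480 FOXA2 peaks lay in none of them and SW620 FOXA2 peaks in 4. The widest, on chromosome 6 from 45396957 to 45423797, spanned 26.8 kb with 5 H3K4me2 and 6 H3K36me3 regions in SW480, against 2 and 0 in SW620. A group of 3 lay on chromosome 5 between 58180992 and 58466384, with 1 H3K4me3 region in each in SW480 and none in SW620. The region on chromosome 17 from 26276626 to 26293772 and that on chromosome 11 from 10668254 to 10683758 had 2 H3K4me2 regions and 1 H3K4me3 region each in SW480 and none in SW620.

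Line-only FOXA2 peaks with H3K27ac in their own line alone numbered 1814 in SW620 and 87 in SW480. Of the first 10 in the SW620 list, 9 overlapped H3K4me2 in SW620 and 2 in SW480. They included peaks on chromosome 11 at 68147826 to 68148144, chromosome 2 at 11494461 to 11494779 and chromosome 10 at 95205378 to 95205696. Of the first 10 in the SW480 list, 2 overlapped H3K4me2 in SW480 and 1 in SW620. They included peaks on chromosome 10 at 132202633 to 132202759 and chromosome 4 at 11157730 to 11157856, both without H3K4me2 in either line.

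The widest H3K4me3 regions were in large part common to the lines. On chromosome 7, a region of 26.5 kb in SW480 (27192922 to 27219470) was matched by one of 26.6 kb in SW620 (27193016 to 27219570). On chromosome 1, the SW480 region from 43409388 to 43430016 was 20.6 kb wide, and 82.0% of it was covered in SW620. The widest of all, 44.1 kb on chromosome 17 from 46652628 to 46696736, was 1 continuous region in SW480, whereas 4 SW620 regions covered 82.2% of it. H3K27ac of SW620 covered 99.0% of the same interval.

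The distribution over chromosomes was close between the lines for histone marks. The share of H3K4me3 regions in SW620 relative to SW480 was within 10% of equal on 22 of 23 chromosomes, those of H3K27ac and H3K36me3 on 21 and that of H3K4me2 on 20. Chromosome 13 had the highest relative shares of H3K27ac, 1.25, and of H3K4me2, 1.16. For FOXA2 the relative share ran from 0.442 on chromosome 18 to 1.60 on chromosome 10, and 5 of 23 chromosomes were within 10% of equal.

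Line-only regions of several marks lay together in stretches of chromosomes, as windows of 5 Mb chosen after the data were seen showed. On chromosome 12 between 90 and 95 Mb, 55 H3K4me2, 44 H3K27ac and 47 H3K36me3 regions were called in SW620 only, against 3, 6 and 8 in SW480 only. This window held 31 FOXA2 peaks in SW620 and 11 in SW480, where the ratio over the whole lists was 2.38. On chromosome 7 between 80 and 85 Mb, 45 H3K36me3 regions were called in SW620 and 0 in SW480, along with 31 and 0 line-only H3K27ac regions. The next windows with an SW620 excess lay on chromosome 6 between 55 and 60 Mb, chromosome 3 between 75 and 80 Mb and chromosome 9 between 5 and 10 Mb. In the opposite direction, chromosome 8 between 130 and 135 Mb had 105 SW480-only and 11 SW620-only H3K36me3 regions, with 18 and 2 for H3K27ac and 26 and 6 for H3K4me2. Its FOXA2 peaks numbered 9 in either line. The other windows with an SW480 excess lay on chromosome 2 between 115 and 120 Mb and between 235 and 240 Mb, chromosome X between 5 and 10 Mb and chromosome 11 between 35 and 40 Mb. In that order, and with SW620 first, they held 7 and 5, 37 and 6, 7 and 18, and 13 and 9 FOXA2 peaks. H3K4me3 did not enter the choice of windows and had few line-only regions in them. Relative to the genome its log2 excess was above 0 in all 5 SW620 windows and in 3 of the 5 SW480 windows. At such counts the added 1 and the genome-wide ratio can set the sign, so no direction is read from it. Chromosome 8 had an excess of 0.48 from 1 SW480-only and 0 SW620-only regions. Chromosomes X and 11 had 1.48 each, from 2 and 2 and from 1 and 1. The SW620 window on chromosome 3 had 1.07 from 3 SW480-only and 2 SW620-only regions.

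**Figure D4:**
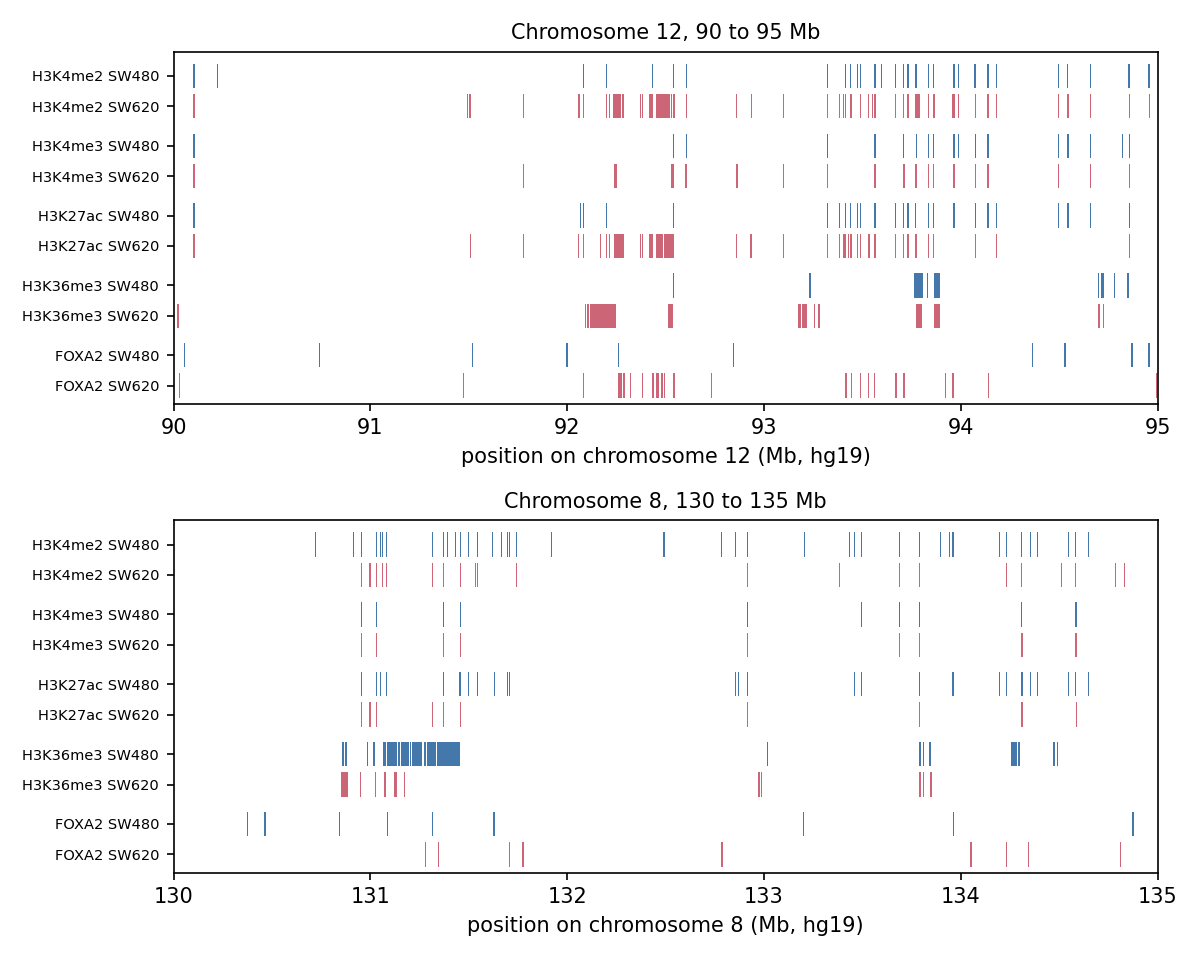
Positions of called regions (horizontal axis, Mb of hg19) for each antibody and cell line (rows) in the window with the strongest SW620 excess, chromosome 12 from 90 to 95 Mb, and in that with the strongest SW480 excess, chromosome 8 from 130 to 135 Mb. Regions narrower than the drawing limit are widened to be visible. The first window held 65 H3K27ac regions in SW620 and 26 in SW480, and the other 10 and 26.

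Over the 428 windows with enough line-only regions, all 3 marks had an excess in SW620 in 107 and in SW480 in 117, together 224. The marks are called on many of the same sites, so their excesses go together to some extent by construction. When the line was swapped at random for whole clusters of line-only regions of the 3 marks within 50 kb, a mean of 183 and at most 217 windows over 100 draws had a common direction. The excess of H3K4me2 and of H3K27ac correlated across windows (Pearson's r 0.75, Spearman's rho 0.71). The correlation was lower between H3K27ac and H3K36me3 (0.48 and 0.43) and between H3K4me2 and H3K36me3 (0.46 and 0.40). These are correlations across genomic windows of the same libraries and partly the same sites, and windows are not independent replicates.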

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

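The alternatives that take equal numbers by list order, one FOXA2 peak width or peaks on H3K4me2, and those for FOXA2 in enhancer-like classes, were chosen after the data were seen. No paired analysis was possible because each group had 1 library, and for the same reason no replicate could be left out. Alternatives for promoter states, gene bodies, gene lists, FOXA2 peaks near genes and the forkhead motif were not run, since no annotation of the build was used. Of the 158 alternative values, 77 lay within the interval of the reported value, or within 1.5 times for a ratio of region numbers. These include chromosomes 1 to 22 and X alone, one FOXA2 peak width, and the ratios of region numbers after merging regions within 1 kb. Several of them could hardly move. Taking the higher-ranked 50% of both lists cannot move a ratio of region numbers. Chromosomes 1 to 22 and X held nearly all regions, for example 5182 of 5207 SW480 FOXA2 peaks. One peak width left the SW620 FOXA2 peaks almost unchanged, since 12371 of 12372 already had it. For each antibody, the chromosomes with the highest and lowest relative share of regions kept their direction when covered length or equal numbers were used. For FOXA2, covered length could not change it, because each list has one peak width. For H3K4me3 the intervals of both relative shares included equality, 1.06 (0.974 to 1.16) on chromosome 3 and 0.884 (0.741 to 1.05) on chromosome 18. The cause of the other changes was not tested, except where the construction of the alternative shows it. Depth limits what a missing H3K4me3 call in SW620 means, since that library had 12791745 tags against 16400013 in SW480. Enrichment limits other missing calls: 27.5% of tags lay in regions in the SW620 H3K27ac library against 58.5% in SW480, and 0.590% in peaks in the SW480 FOXA2 library against 2.25% in SW620.

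Values follow with the SW480 list first and the SW620 list second. Requiring an overlap of 50% of the shorter region gave 74.7% and 67.7% for H3K4me2, 81.2% and 91.2% for H3K4me3, 66.9% and 71.7% for H3K27ac, and 57.4% and 63.2% for H3K36me3. Requiring 50% of both regions gave 67.4% and 60.9%, 77.6% and 87.0%, 58.3% and 61.6%, and 30.5% and 35.3% for the marks in the same order. For FOXA2 this rule left 0.0192% and 0.00808%, because peaks of 127 bp cannot cover 50% of peaks of 319 bp. Counting regions within 1 kb gave 77.9% and 71.3% for H3K4me2, 68.8% and 74.5% for H3K27ac, 72.8% and 79.2% for H3K36me3, and 5.84% and 2.39% for FOXA2. It also gave 8.39% and 54.7% of FOXA2 peaks on H3K4me2, and 6.20% and 36.4% on H3K27ac.

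FOXA2 peaks are ranked by list order, which need not follow peak strength. The higher-ranked 50% of each histone list was shared more often, with 94.8% and 91.5% for H3K4me2, 97.6% and 98.6% for H3K4me3, 83.7% and 86.4% for H3K27ac, and 82.6% and 87.9% for H3K36me3. For FOXA2 it was 2.91% of the SW620 list. In that part of the lists, 4.96% and 59.1% of FOXA2 peaks lay on H3K4me2, and 39.4% of the SW620 peaks on H3K27ac. Equal numbers from both lists gave 74.8% and 74.8% for H3K4me2, 89.9% and 90.1% for H3K4me3, 70.7% and 72.2% for H3K27ac, 70.4% and 68.3% for H3K36me3, and 3.28% and 3.28% for FOXA2. The gaps between the lines for H3K4me2, H3K4me3 and H3K27ac thus narrowed when list length was equal, and that for H3K36me3 turned. The narrowing follows largely from the construction, because similar numbers of regions overlapped from either full list. For H3K4me3 these were 15173 of 18296 SW480 and 15197 of 16315 SW620 regions. The gaps between the reported shares of these 3 marks thus reflect list length in large part. Equal numbers by list order gave 74.8% and 74.8%, 90.1% and 90.4%, 70.6% and 72.1%, and 70.4% and 68.3% for H3K4me2, H3K4me3, H3K27ac and H3K36me3. Under the same rule by width, promoter-like H3K27ac was shared in 82.8% and 94.7% and enhancer-like in 43.7% and 38.6%. With H3K4me3 of either line within 1 kb, the enhancer-like shares were 39.5% and 37.0% and the promoter-like share of SW620 was 94.3%.

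At FOXA2 peaks called in SW620 only, H3K27ac of SW620 and of SW480 covered 39.8% and 26.2% in the higher-ranked 50% of the lists, 40.8% and 26.2% with equal numbers of peaks, and 36.7% and 26.8% when H3K27ac within 1 kb counted. At peaks called in SW480 only, H3K27ac of SW480 and of SW620 covered 3.99% and 2.63% in the higher-ranked 50%, and 4.97% and 3.72% within 1 kb. The ratio of FOXA2 peak numbers was 21.9 for peaks on H3K4me2. With the higher-ranked 50% of SW620 peaks, enhancer-like H3K27ac regions held a peak in 4.12% of SW480-only, 18.5% of shared and 16.8% of SW620-only cases, lower because fewer peaks entered.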

Other observations

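The tests of depth, random placement, immunoprecipitation, promoters and acetylated chromatin and all tests of the 5 Mb windows were chosen after the result was seen. Those of peak width, region width and chromosomes were fixed before their result was seen, though after the pattern. The values by list order and those on H3K4me2 at line-only H3K27ac regions were also chosen after the data were seen.

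Line-only acetylation came with different H3K4me2 in the opposite line. Of the SW480-only H3K27ac regions, 82.7% (81.8 to 83.5) overlapped H3K4me2 in SW480 and 52.0% (50.9 to 53.1) overlapped it in SW620, where H3K27ac was not called. Of the SW620-only H3K27ac regions, 74.4% (73.3 to 75.5) overlapped H3K4me2 in SW620 and 18.1% (17.2 to 19.1) in SW480. H3K4me3 lay on 39.4% (38.3 to 40.5) of the SW480-only regions in SW480 and 24.5% (23.5 to 25.5) in SW620. For SW620-only regions it was 10.6% (9.85 to 11.4) in SW620 and 4.22% (3.74 to 4.76) in SW480. The H3K27ac libraries that define these classes had 58.5% of tags in regions in SW480 and 27.5% in SW620.

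The FOXA2 lists were divided by their order into 10 equal parts. H3K4me2 lay under 62.7% (60.0 to 65.3) of the first part of the SW620 list and 34.3% (31.7 to 37.0) of the last part, and H3K27ac under 44.1% (41.4 to 46.9) and 23.1% (20.8 to 25.5). The share on H3K4me3 was lowest in the first part at 9.21% (7.72 to 10.9), highest in the sixth at 15.4% (13.5 to 17.5) and 11.6% (9.89 to 13.5) in the last. In SW480 the share on H3K4me2 was 7.49% (5.52 to 10.1) in the first part, lowest in the third at 3.08% (1.90 to 4.94) and 7.10% (5.20 to 9.64) in the last. For H3K27ac these were 9.98% (7.69 to 12.9), 13 of 520 peaks (1.47 to 4.23%) and 5.76% (4.06 to 8.10).

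SW480 FOXA2 peaks rarely lay on H3K4me2 of their own line. Their smaller width is argued against, since peaks set to the SW620 width reached 5.93% (5.32 to 6.61), below the 25.8% that 50% of the SW620 share would be. Depth is argued against by a ratio of total tags, SW480 over SW620, of 1.08. Uniform placement of the whole list is argued against by an observed 5.61% against a highest value of 3.59% over 100 random placements. Of the 292 peaks on H3K4me2, 82 were among the 236 shared peaks, and the SW480-only peaks reached 4.22% (3.70 to 4.82). Random placement was uniform over each chromosome, so it cannot decide whether most SW480-only peaks were placed without regard to the marks. The fragment length was 108 bp in the SW480 and 164 bp in the SW620 FOXA2 library. Filtering by input removed 3651 of 8976 putative peaks in SW480 and 6250 of 19333 in SW620. Weak immunoprecipitation in the SW480 library, with 0.59% of tags in peaks against 2.25%, cannot be told apart from lower FOXA2 occupancy in this line, because each line has 1 FOXA2 library. Lower occupancy may thus be proposed as a hypothesis only.

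SW620 FOXA2 peaks lay in SW620-only H3K27ac regions more often than in SW480-only ones, by 19.7 percentage points. Region width is argued against because SW620-only regions were the narrower (median 1519 against 1763 bp) while peaks lay more often in wider ones (35.4% above and 18.0% up to the SW620-only median); matched on width, the difference was 19.7 points (SE 0.631). The SW620-only share was higher on 23 of 23 chromosomes, which argues against copy number of a few chromosomes. Among regions without H3K4me3 the difference was 18.8 points, so a different share of promoters is argued against as the whole cause. Whether FOXA2 peaks lie wherever SW620 chromatin outside promoters is acetylated remains open. Shared regions without H3K4me3 held a peak in 29.9% of cases and SW620-only ones in 26.5%. The shared ones were wider, with a median of 2294 bp against 1515 bp, and these classes were not matched on width. Since peaks lay more often in wider regions, these shares cannot decide the question.

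Windows of 5 Mb in which line-only regions of 3 marks share a direction numbered 34 at a log2 excess beyond 1 in each mark. When the line was swapped at random for whole clusters of line-only regions within 50 kb, which keeps marks on one site together, the highest number over 100 draws was 18, which argues against chance clustering of such sites; larger units were not tried. Complete loss of the DNA of whole windows in the opposite line is argued against. Over the 10 named windows together, 72.4% (64.6 to 79.0) of the 145 H3K4me3 regions of the line with the excess were found in both lines. By window the share was lowest on chromosome 7 between 80 and 85 Mb, at 6 of 12 regions. Deletion of part of a window would leave such regions in place and was not tested. Extra copies in SW620 cannot be told apart from regulation in its 5 windows: relative to the genome, the ratio of H3K4me3 regions was 1.42 (1.00 to 2.01) and that of H3K27ac regions 3.14, and the interval includes the 1.57 set as the bound. H3K27ac was among the marks by which these windows were chosen, and H3K4me3 was not. The H3K27ac ratio, and the bound set at 50% of it, are therefore raised by that choice. Extra copies in SW480 in its 5 windows, and loss of some copies in either line, were not tested. Domain-wide regulation may be followed up as a hypothesis with the input libraries.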
